A study of Caenorhabditis elegans with 4 samples.

How the data were processed

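Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was carried out for LIN-53 in late embryos of wild-type N2 Caenorhabditis elegans, the standard laboratory strain. Per the labels' protocols, embryos from gravid adults were kept for 3.5 hours in M9 buffer before freezing, the worms were grown at 20 °C, and ground material was fixed for 10 minutes in 1% formaldehyde and sonicated. LIN-53 was precipitated with SDQ2370, an affinity-purified rabbit polyclonal antibody. Libraries were amplified for 18 cycles and size-selected to 250 to 350 bp. There were 4 samples, which the titles divide into 2 LIN-53 ChIP samples and 2 input samples, both numbered 1 and 2. The input samples have no list of their own here and entered no calculation; whether the authors' peak calls used them is not given in the sources used here.

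The values were 3 peak lists, 1 for each ChIP sample and 1 combined list for the series. Per the file headers, positions are on the WormBase WS220 build, and comment lines record that the lists were lifted from another build. Those comments mark 4 peaks of replicate 1, 5 of replicate 2 and 9 of the combined list as altered in internal structure, and the width of each of these peaks differed between the comment and its row. The only measurement per peak is a score given by the authors, whose unit is not given in the sources used here. Scores ran from 50.01 to a ceiling of 3100 over the 3 lists. The source column names MA2C while the peak names begin with MACS, so the caller is not settled by the files. Per the submitters' processing notes, reads were aligned with BWA. Versions, the calling threshold, the treatment of reads with several genomic matches, and the way the combined list was made are not given in the sources used here. The lists hold no read counts, so the depth of each library is unknown, and a score may rise with depth as well as with enrichment. Scores were therefore used to rank peaks within a list. Where the scores of both replicates are set side by side, they may carry the depth of each library.

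Peaks were taken as deposited, with no further filter. In 6 peaks of replicate 2 and 6 of the combined list the start was a dot; start 1 was used for overlaps and midpoints, and these peaks were left out of widths. Lengths of the WS220 chromosomes were not used. The span of each chromosome was counted from base 1 to the last base called in any list, a lower bound on its length that summed to 100.15 Mb. Peaks of 2 lists counted as shared when they overlapped by at least 1 bp. The chance overlap came from 100000 circular shifts of one list, with 1 random offset per chromosome (two-sided permutation test, smallest p 1e-05). Scores and widths were compared over one-to-one overlapping peaks with permutation tests of 100000 pairings or sign changes. Peak density on the X chromosome against the autosomes, and the share of autosomal peaks in the central 33.3% of each span, were tested with two-sided exact binomial tests against span. Differences between the replicates were tested with two-sided Fisher's exact tests. Adjusted p-values are Benjamini-Hochberg values within the family named beside them. Intervals are 95% Wilson intervals for shares and exact Poisson intervals for densities, and they cover counting error only. Peaks are not independent of their neighbours, and the p-values rest on peaks or windows, so they measure no spread between samples. The labels do not say whether the ChIP samples came from separate cultures, so a difference between them may be technical.

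Calculations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9. The overlap, density and central-share calculations were tested on simulated lists: 400 of 400 planted shared peaks were found, a planted X-to-autosome density ratio of 0.25 came back as 0.252 on average, and a planted central share of 25% as 25.1%. The planted shared peaks were copies moved by less than a peak width, so finding them was certain. Simulated peaks were placed independently, so these checks do not cover peaks that lie close together. The main tests, gene lists and rule for named items were fixed before the data were examined. The Fisher's exact tests between replicates, the score comparison of X with autosomes, the shares by score quartile, the 1 Mb windows, the spacing of peaks and the tests on chromosome tips were added later. The rule names the 15 highest-scoring combined peaks found in both replicates, and the 5 highest-scoring peaks of each replicate that the other lacks. The other left-tip peaks, the densest windows, the largest clusters and an evenly spaced run are named outside this rule and were chosen after their values were seen. The planned comparisons with gene starts, gene lists, non-coding gene classes and sequence motifs, and gene number as an expectation for chromosomes, are not analysed here: the gene table at hand is on the WBcel235 assembly, and positions were not carried between builds. Peaks are named by WS220 position only, and whether they lie in genes is not reported. Alternatives were other overlap rules, higher-scoring peaks only, each replicate list alone, a wider central region, and, added after seeing the data, leaving out peaks without a start, merging close peaks and a shift-based test of the central share.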

Results

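LIN-53 is a worm member of a family of histone-binding proteins that were first found with the retinoblastoma protein. It is a subunit of several chromatin complexes, among them the DRM repressor complex and the nucleosome remodelling and deacetylase complex. Its binding sites in late embryos were mapped by ChIP-seq in 2 ChIP samples, and 2 input samples were sequenced beside them. Replicate 1 had 1047 peaks covering 1.67 Mb, and replicate 2 had 1001 peaks covering 1.88 Mb. The combined list had 1221 peaks covering 2.44 Mb, or 2.43% of the 100.15 Mb called span. The median peak was 1372 bp wide in replicate 1, 1579 bp in replicate 2 and 1754 bp in the combined list. The median score given by the authors was 222.8 in replicate 1, 99.5 in replicate 2 and 170.9 in the combined list. The lists give no read counts, so the depth behind each peak is unknown.

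The first comparison the design implies is between the replicates. Fewer than 50% of the LIN-53 sites in each list were found in the other, and high-scoring sites were shared more often than low-scoring ones. Of the replicate 1 peaks, 465 of 1047 overlapped a replicate 2 peak (44.4%, 95% interval 41.4% to 47.4%). Of the replicate 2 peaks, 471 of 1001 overlapped a replicate 1 peak (47.1%, 44.0% to 50.2%). Both shares count the same overlap, from each side. Their mean of 45.7% ± 1.87 (SD, n = 2) therefore gives no spread between independent measurements. Circular shifts of the peaks along their chromosomes gave 3.88% and 4.08% on average. The observed overlap was 11.4 and 11.5 times these means (permutation test, p = 1e-05 in both directions, the smallest it can give). The shifts can place peaks anywhere along the span. They do not allow for regions where peaks of any kind are more likely, so the excess is not specific to LIN-53. In the highest score quartile of replicate 1, 91.6% of 262 peaks were shared (87.6% to 94.4%), against 11.8% of 262 (8.46% to 16.3%) in the lowest quartile. In replicate 2 the corresponding shares were 76.4% (70.8% to 81.2%) and 26.3% (21.2% to 32.1%).

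Over the 454 peaks that overlapped one to one, scores rose together in the replicates, with Spearman's rho 0.62 and Pearson's r 0.69 (permutation tests of pairings across peaks, p = 1e-05 for each). These correlations are across peaks, which are not independent replicates. The score was higher in replicate 1 at 412 of the 454 peaks (90.7%), with a median log2 ratio of 1.85 (95% bootstrap interval 1.72 to 1.95). Because a score may also grow with depth, this ratio does not separate stronger enrichment from a deeper library. The paired peaks were slightly wider in replicate 1, by a median log2 ratio of 0.07 (0.05 to 0.10; sign permutation test of the median, p = 1e-05). The mean log2 ratio of 0.02 ± 0.43 (SD over peaks) did not pass the same kind of permutation test (p = 0.30). It passed under stricter pairing, at 0.06 with at least 50% overlap of both peaks (431 pairs, permutation p = 0.00056) and at 0.10 with midpoints within 200 bp (314 pairs, permutation p = 1e-05). The 50% rule leaves out pairs of very unlike widths, and the midpoint rule leaves out pairs with displaced centres. These values therefore describe selected pairs and do not settle whether the mean width differs.

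**Figure D1:**
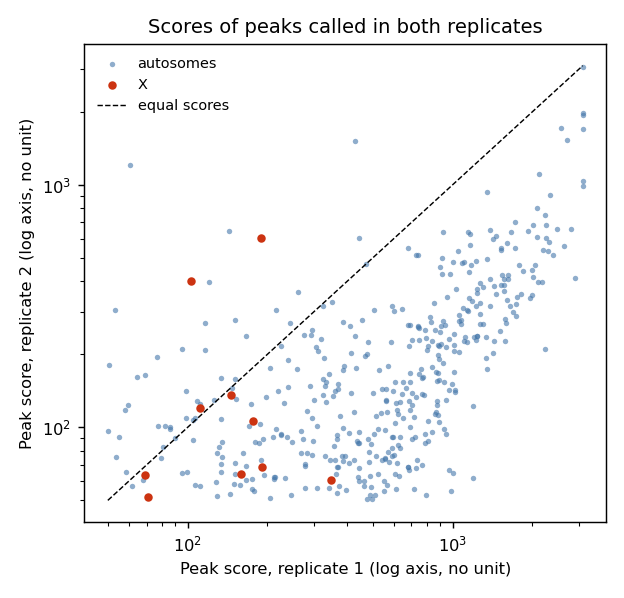
Scores given by the authors at the 454 LIN-53 peaks that overlap one to one, replicate 1 on the x axis and replicate 2 on the y axis, both logarithmic and without unit. Each point is a peak, the dashed line marks equal scores, and 412 points lie below it.

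The combined list shared more peaks with replicate 1 than with replicate 2. It held 876 of the 1047 replicate 1 peaks (83.7%, 81.3% to 85.8%) and 699 of the 1001 replicate 2 peaks (69.8%, 66.9% to 72.6%). Of its 1221 peaks, 460 (37.7%, 35.0% to 40.4%) overlapped a peak of both replicates, 416 (34.1%) overlapped replicate 1 only, 231 (18.9%) replicate 2 only and 114 (9.34%) neither. The median combined score was 570.8 for peaks found in both replicates, 125.2 for those found in replicate 1 only, 80.2 for those found in replicate 2 only and 66.2 for those found in neither.

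The 15 highest-scoring combined peaks that both replicates contained lay on every autosome, with none on the X chromosome. Only 9 of the 460 combined peaks found in both replicates were on X, so their absence among 15 says little about strength. Of the 15, 4 each lay on chromosomes I, II and III, 2 on IV and 1 on V. At the score ceiling of 3100 were 6 sites. They were on chromosome I from 533842 to 537770, on III from 1618163 to 1620748, from 4756541 to 4758052 and from 7853903 to 7855722, on IV from 4388985 to 4391691, and on V from 10896568 to 10898056. The site on V was also the highest-scoring peak of replicate 2, with 3055, and stood at the ceiling of 3100 in replicate 1. The site on III that begins at 4756541 stood at 3100 in replicate 1 and at 1037 in replicate 2. The next sites were on chromosome II from 15007978 to 15011540, with a combined score of 2843, and on I from 12531587 to 12533072, with 2784. The remaining 7 ranged from 2428 to 2737. The widest of the 15 spanned 5464 bp on chromosome I from 12964622 to 12970085. In replicate 1 these 15 sites scored 2112 to 3100, and in replicate 2 they scored 413.4 to 3055, counting the higher of the 2 replicate 2 peaks under the site on II that begins at 15007978.

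The distribution over chromosomes asks whether LIN-53 binding differs between the X chromosome, which is under dosage compensation in hermaphrodites, and the autosomes. The X chromosome carried few LIN-53 peaks in every list. The combined list had 3.28 peaks per Mb on X (58 peaks) and 14.1 per Mb on the autosomes (1163 peaks), a ratio of 0.23 (95% interval 0.18 to 0.30; exact binomial test against span, p = 4.63e-42). The ratio was 0.14 (0.10 to 0.20) in replicate 1 and 0.32 (0.25 to 0.42) in replicate 2, with a mean of 0.23 ± 0.13 (SD, n = 2). Among the combined peaks found in both replicates, 9 of 460 were on X, a ratio of 0.09 (0.05 to 0.18), and among the replicate 2 peaks that replicate 1 lacked, 55 of 530, a ratio of 0.54 (0.41 to 0.71). X peaks also scored lower than autosomal peaks, with a median of 78.6 against 179.9 in the combined list (permutation test on ranks, p = 1e-05, the smallest it can give), 109.4 against 231.5 in replicate 1 (permutation p = 1e-05) and 83.6 against 101.1 in replicate 2 (permutation p = 0.012). In replicate 2 the difference passed neither among the peaks that replicate 1 shared (87.7 against 148.6, permutation p = 0.088) nor among those it lacked (83.61 against 80.85, permutation p = 0.63).

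The share of peaks on X differed between the replicates. It was 2.96% in replicate 1 (31 of 1047) and 6.49% in replicate 2 (65 of 1001; Fisher's exact test, adjusted p = 0.00023 over 6 comparisons of the replicates). Shared peaks are the same sites in both lists, so the comparison was repeated on the others. Among peaks that the other replicate lacked, 3.61% of 582 in replicate 1 and 10.4% of 530 in replicate 2 were on X (Fisher's exact test, adjusted p = 1.56e-05).

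Every autosome was denser than X in each list, and the autosomes also differed from one another. Chromosome III was the densest in the combined list, with 17.9 peaks per Mb (15.8 to 20.3), and V the sparsest autosome, with 9.96 per Mb (8.65 to 11.4). Relative to the other autosomes, the density was 1.34 times as high on III and 0.64 times as high on V, with exact binomial p-values adjusted over 5 autosomes of 0.00015 and 8.76e-09. Chromosome V was below and III above the other autosomes in both replicates as well, with adjusted exact binomial p = 1.03e-07 and 3.85e-06 in replicate 1 and 0.0023 and 0.035 in replicate 2. Chromosome I was denser than the other autosomes in the combined list (ratio 1.26, adjusted exact p = 0.0021) and in replicate 1 (ratio 1.27, adjusted exact p = 0.0029), and had a ratio of 1.17 in replicate 2 that did not pass (adjusted exact p = 0.052). Chromosomes II and IV passed in replicate 2 alone, with ratios of 1.22 and 0.80 (adjusted exact p = 0.024 and 0.023), and had ratios of 1.08 and 0.88 in the combined list (adjusted exact p = 0.27 and 0.11).

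**Figure D2:**
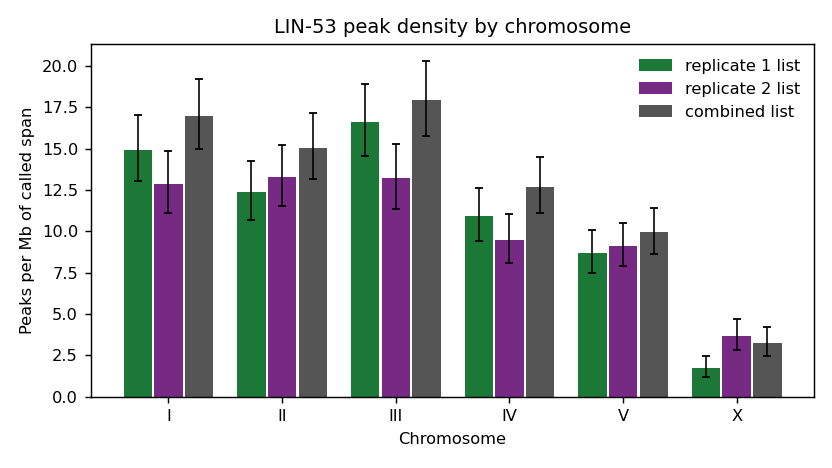
LIN-53 peaks per Mb of called span (y axis) on each chromosome (x axis) in the replicate lists and the combined list; error bars are 95% exact Poisson intervals for counting error. X lies lowest in every list, at 1.75, 3.67 and 3.28 peaks per Mb.

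The next comparison asks where along the autosomes the peaks lie, since the arms and centres of worm autosomes differ in genes and chromatin. Replicate 1 showed no preference, whereas replicate 2 peaks were sparse in the centres. The central 33.3% of the autosome spans held 34.4% of replicate 1 peaks (350 of 1016; 31.6% to 37.4%; exact binomial p = 0.46) and 22.6% of replicate 2 peaks (212 of 936; 20.1% to 25.4%; exact binomial p = 9.30e-13). With circular shifts, which keep neighbouring peaks together, the permutation p was 0.53 for replicate 1 and 0.0042 for replicate 2. The binomial and Fisher's exact tests count each peak as independent, so their p-values are too small where peaks lie close together. The difference between the replicates passed Fisher's exact test (adjusted p = 2.48e-08), and the mean share was 28.5% ± 8.34 (SD, n = 2). In replicate 2 the central share was below 33.3% on each autosome, from 15.8% on II to 25.3% on IV. The shared peaks are the same sites in both lists, though not all pair one to one. Their central share was 34.9% as counted in replicate 1 (159 of 455) and 34.5% as counted in replicate 2 (159 of 461). Of the autosomal peaks that replicate 2 alone contained, 53 of 475 were central (11.2%, 8.63% to 14.3%), against 191 of 561 (34.0%, 30.2% to 38.1%) for replicate 1 alone (Fisher's exact test, adjusted p = 7.08e-18).

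The combined list lay between the replicates, with 28.9% of 1163 autosomal peaks in the centres (26.4% to 31.6%; exact binomial p = 0.0012). This call depended on the peaks counted and on the test. It was lost in replicate 1 alone, among the combined peaks found in both replicates (35.0%, exact binomial p = 0.45), among all combined peaks with above-median scores (32.9%, exact binomial p = 0.86) and with close peaks counted as 1 (30.6%, exact binomial p = 0.081). It was also lost when circular shifts, which keep neighbouring peaks together, replaced the binomial test (permutation p = 0.064). The deficit among peaks of replicate 2 alone passed with circular shifts as well (permutation p = 0.0011). On X, 15 of 58 combined peaks were central (25.9%, 16.3% to 38.4%), which did not differ from 33.3% (exact binomial p = 0.27).

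**Figure D3:**
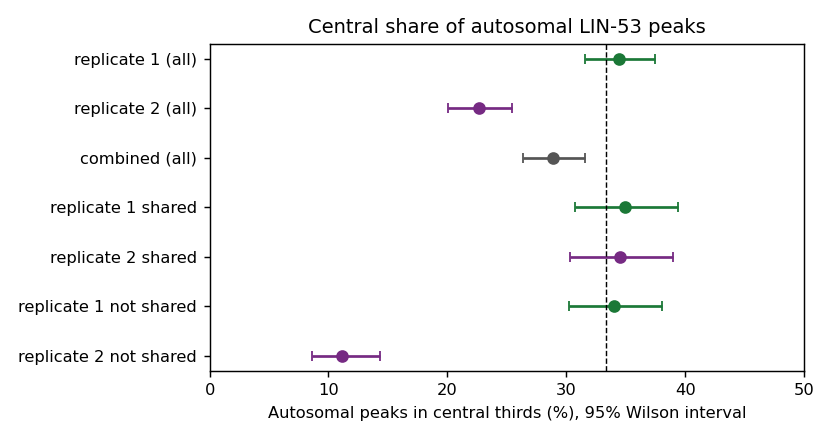
Percentage of autosomal LIN-53 peaks in the central 33.3% of the chromosome spans (x axis) for each list and for peaks shared or not shared with the other replicate (y axis); points are shares, bars 95% Wilson intervals, and the dashed line the share expected from span. The shared peaks of both replicates are the same sites. Only replicate 2, its unshared peaks and the combined list have intervals below the line.

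Counted in full 1 Mb windows, the combined list held 1 to 27 peaks per window over 97 windows, with a median of 14 in the 80 autosomal windows. The 3 windows with 27 peaks, picked after their values were seen, were the first Mb of chromosome I, the Mb of III that begins at 11000001 and the Mb of IV that begins at 4000001. Replicate 1 had 12, 19 and 15 peaks in these windows and replicate 2 had 23 in each. Across autosomal windows the replicate counts correlated with Spearman's rho 0.45 (permutation p = 3e-05) and Pearson's r 0.36 (permutation p = 0.0014). Pearson's r was 0.37 without the 2 windows farthest from the median of replicate 1. Including the X windows gave rho 0.66 and r 0.55 (permutation p = 1e-05 for each), a value that partly reflects the gap between X and the autosomes. These 4 correlations are across windows, not samples, and the largest of their adjusted p-values was 0.0014.

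**Figure D4:**
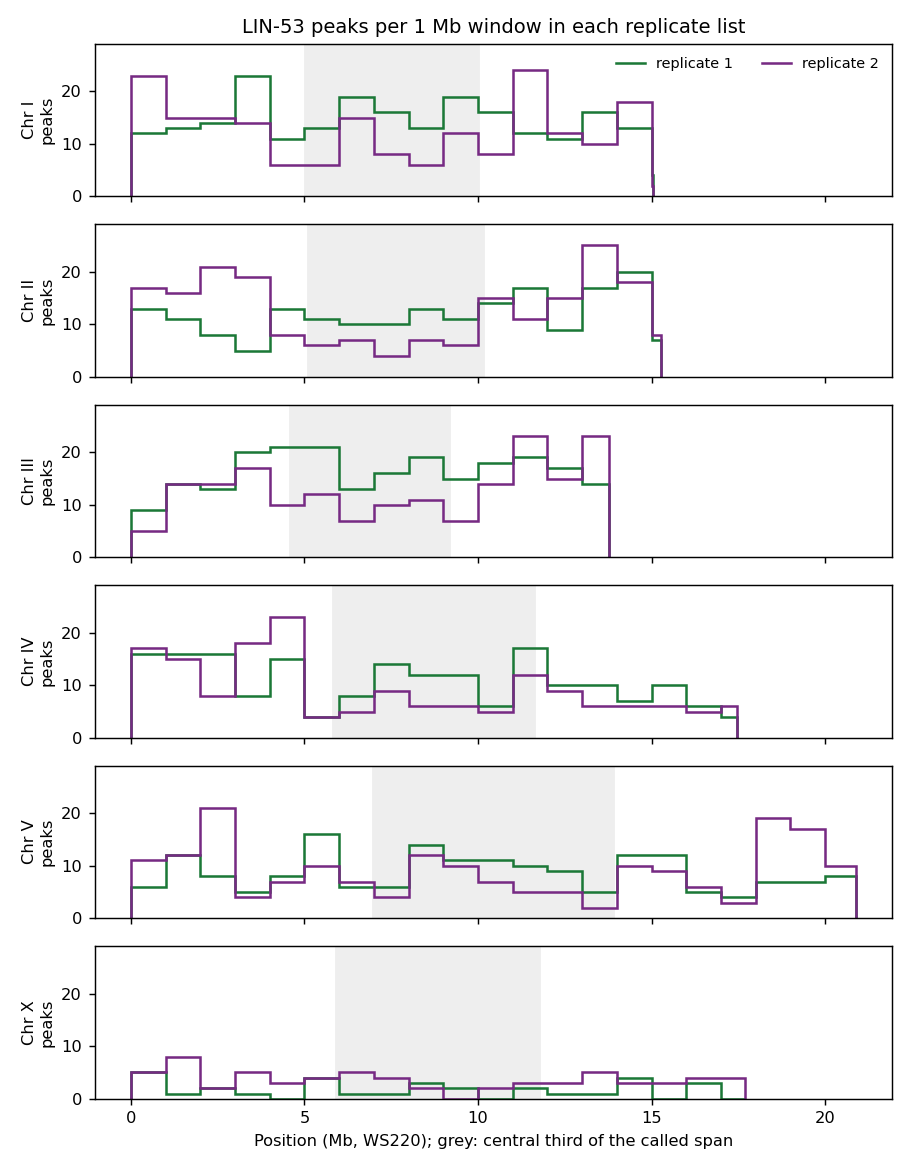
LIN-53 peaks per 1 Mb window (y axis) along each chromosome (x axis, position in Mb on WS220) in replicate 1 and replicate 2; grey marks the central 33.3% of each called span and the last window of each chromosome is partial. Replicate 2 exceeds replicate 1 in the outer windows of several autosomes, such as the first Mb of chromosome I with 23 against 12 peaks.

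The left tip of every chromosome carried a peak in replicate 2 and in the combined list, and in replicate 1 on none of the 6. The tips were singled out after their values were seen. They are the 6 peaks of replicate 2 and the 6 of the combined list whose start was a dot, so only their ends are given. These peaks ended between 629 and 1506 bp from the first base in replicate 2. Their replicate 2 scores were 2686 on X, 2395 on I, 1942 on V, 741.2 on IV, 653.1 on III and 557.6 on II, which placed those of X, I and V among the 8 highest-scoring peaks of that list. In the combined list the scores were 1025, 1059, 682.0, 543.0, 354.5 and 136.3 in the same order. The first replicate 1 peak began at 6779 on V, 10068 on X, 16492 on I, 23354 on II, 125822 on IV and 188207 on III.

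Of the other strong peaks that a single replicate contained, the highest of replicate 2 was on chromosome II from 693511 to 699585, with a score of 2747. Its combined score was 191.4, and the nearest replicate 1 peak was 41600 bp away. The peak on III from 7443851 to 7449317 scored 1959 in replicate 2 and overlapped no combined peak. In replicate 1, the highest were on I from 13609742 to 13614404, at the ceiling of 3100 and with a combined score of 2537, and on IV from 12022040 to 12025778, with 2629 and a combined score of 1655. The other 3 of the 5 highest of replicate 1 scored 954.1 on V, 848.1 on IV and 817.6 on III, and each had a combined peak.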

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

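Of 49 alternative values, 36 kept their direction and their side of the threshold, or stayed within the counting error. These include central shares on X, which passed in no setting, and Pearson's r beside Spearman's rho for the same pairs. The count is therefore no measure of robustness. Of the others, 3 lost their call, 8 moved beyond the counting error and 2 reversed. The reversals were the autosomal central shares in replicate 1 alone and in combined peaks found in both replicates. The overlap of the replicates stayed above chance under every rule tried, from 30.0% (midpoints within 200 bp) to 51.3% (above-median scores) of replicate 1 peaks. In the replicate 2 list alone and the replicate 1 list alone, the X-to-autosome ratio was 0.32 and 0.14, as given above. No combined list was remade with a replicate left out. It was 0.05 in the combined peaks with above-median scores and 0.28 when peaks with gaps under 10 kb were counted as 1, so X was below the autosomes throughout. The central share of autosomal peaks in the combined list kept its call with the central 50% of each span (44.2%, exact binomial p = 8.38e-05) and without the peaks that have no start (29.02%, exact p = 0.0018), and did not hold under the other alternatives, replicate 2 alone excepted. The central share was 34.4% in the replicate 1 list alone and 22.6% in the replicate 2 list alone. It was 35.0% in combined peaks found in both replicates, 32.9% in those with above-median scores (exact binomial p = 0.86), 30.6% with close peaks counted as 1 (exact p = 0.081), and 28.9% with a permutation p of 0.064 under circular shifts; the cause was not tested for the last 3. The last 2 settings, and leaving out peaks without a start, were chosen after seeing the data. With above-median scores, the shares of combined peaks in both replicates and in replicate 2 only moved from 37.7% and 18.9% to 44.0% and 9.82%. With 50% overlap of both peaks, the shares in both and in neither were 33.4% and 11.6%. With midpoints within 200 bp, the shares in both, replicate 1 only, replicate 2 only and neither were 23.3%, 29.4%, 22.2% and 25.06%, since fewer peaks count as shared under stricter rules. No paired analysis was possible because the input samples have no peak list here, so the replicate numbers shared by input and ChIP pair nothing. Alternatives tied to gene starts, gene lists, non-coding genes, motifs and gene number were not run. Without read counts, depth cannot be separated from enrichment, and a peak missing from a list is not shown to lack binding.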

Other observations

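The tests on the left tips of the chromosomes were chosen after the result was seen.

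Combined peaks lay closer together than their Mb-scale density alone gave. Of neighbouring combined peaks on a chromosome, 17.3% had midpoints under 10 kb apart, against 14.3% on average (95% range 12.6% to 16.1%) when each midpoint was drawn anew within its own 1 Mb window (permutation p = 0.0013, 10000 draws). The share was 15.1% in replicate 1 (drawn mean 12.6%, permutation p = 0.0058) and 18.5% in replicate 2 (drawn mean 12.8%, permutation p = 0.0001, the smallest it can give). Merging peaks with under 10 kb between the end of one and the start of the next, a looser measure than midpoints, left 980 clusters, 45 of them with 3 or more peaks. The largest held 5 peaks each, on chromosome II from 13817243 to 13829592 and on V from 8883862 to 8898879. Density differences on the scale of 1 Mb are therefore not enough for this spacing. Whether the close peaks are neighbouring genes, parts of one wide site or split calls was not tested.

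Peaks at the left tips of 6 of 6 chromosomes were called in replicate 2 and in replicate 1 on none. Each of these replicate 2 peaks had a dot as its start. Generally weaker scores in replicate 1 are argued against, since shared peaks scored higher there (median log2 ratio 1.85). Of 50 other replicate 2 peaks at least as strong as the weakest tip, 40 were found in replicate 1. The ratio covers only peaks called in both lists, so a weaker signal at the tips alone stays open. A removal of rows after numbering is excluded, since 0 of the running peak numbers of replicate 1 are missing. A removal before numbering stays open. The tips of worm chromosomes are telomere repeats, so a greater pick-up of repeated DNA in replicate 2 may be the source. So may less of it in its input, if that was used. Such a source should reach the right tips as well. These were not examined, because the lengths of the chromosomes were not used. The search for evenly spaced peaks, as a tandem repeat would give, found 1 run in replicate 2 and 0 in replicate 1 (exact binomial p = 0.49), too few to decide, and as both samples are replicates of one group, no biological explanation was tested.

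Autosomal replicate 2 peaks were less often central than those of replicate 1. Peaks below the median score are not the whole source. Among peaks with above-median scores the central share was still 25% in replicate 2 against 35.9% in replicate 1 (Fisher's exact test, p = 0.00020). The above-median peaks begin at a score of 99.5 in replicate 2, whose lowest score was 50.14, and at 222.8 in replicate 1. Weak calls among the above-median peaks of replicate 2 therefore stay open as a source. Shared peaks are the same sites in both lists, so a difference can come almost only from the unshared peaks of one or the other. The unshared peaks of replicate 1 had a central share of 34.0%, against 34.5% for the shared peaks as replicate 2 lists them (Fisher's exact test, p = 0.89), and the unshared peaks of replicate 2 had 11.2%, consistent with a deficit in the latter. Whether these arm and tip peaks are LIN-53 binding at heterochromatin that replicate 1 missed, or background, stays open without read counts.

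The evenly spaced run in replicate 2 lay on chromosome IV from 4921271 to 4927285. It had 3 peaks whose starts were 2277 bp apart in both steps, with scores of 312.1 to 375.4, and replicate 1 had none of them.

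The combined score was lower than the replicate 1 score at 535 of 870 one-to-one peaks (61.5%), and lower than the replicate 2 score at 165 of 683 (24.2%).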
